A study of Homo sapiens with 4 samples.

How the data were processed

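Per the labels, ELF5 was immunoprecipitated from sonicated T47D nuclei in 3 replicates, and 1 input sample was sequenced; the libraries were size-selected and sequenced on an Illumina HiSeq. The labels do not say whether the replicates came from separate cultures. The antibody is given per sample, while the protocol text names antibodies against other factors in other cell lines. The authors' deposited list is on hg19, per the file headers and the submitters' processing notes, and its track name refers to IDR and to 1-3, which can be read as replicates 1 to 3 or as replicates 1 and 3. The list has no IDR column, and whether its peaks passed an IDR threshold could not be checked. The aligner, the peak caller, its threshold, the treatment of the input and whether peaks were called on pooled replicates are not given in the sources used here.

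The authors' deposited score of each peak equals the whole part of 10 times its −log10 p in all 115384 rows. The authors' deposited −log10 p and −log10 q of each peak were used as given. The deposited signal value, with no unit in the file, behaves as a fold enrichment, a ratio of ChIP to local background. The score, fold, p and q of each peak are the authors', and were used to describe, rank and filter peaks within this list. The fold and p also served to recover pileups and backgrounds, on which the intervals and the comparisons with background rest. No column held values per sample.

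The fold and p of each peak were used to recover the fragment pileup and the background behind them. A single factor of 0.910 on whole pileups, a pseudocount of 1 and a Poisson tail gave the p of all 115384 peaks within 0.001 of −log10 p, and 95 peaks had a second pileup within that tolerance. The lowest background was 1.81 fragments, at 8.55% of peaks. The background was a whole number at 39.8% of peaks and came in steps of a 1 kb window at 31.6% and of a 10 kb window at 20.0%, for a fragment of 135 bp, the smallest peak width, each to within 0.001 fragments. These quantities are inferred from the deposited values. The total reads per sample are unknown here. In a test on 20000 simulated peaks with a factor of 0.7731, 100% of pileups were recovered. With a factor of 0.8, whose products with pileups are often whole, 80% were recovered, and 99.99% of those within the tolerance.

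Intervals of a fold are exact Poisson 95% intervals of the pileup with the background fixed. Bands and their Giemsa classes on hg19 were taken from the table bundled with circlize 0.4.16 in R 4.3.3, and the ends of 24 chromosomes matched the hg19 lengths in GenomeInfoDb 1.38.1. Comparisons used chromosomes 1 to 22 and X. The share of summits in light bands was tested by 10000 rotations of the summits along the euchromatic bands of each chromosome, differences between bands by 10000 permutations of band labels, correlations by 100000 permutations, and spacing by 1000 placements within bands. Bands in the terminal comparison had at least 20 peaks, and ranked bands were at least 2 Mb long. On simulated data without an effect, 6% of rotation tests, 7% of band permutations and 6.5% of correlation tests had p under 0.05 in 200 runs each. The simulated bands were independent of each other, unlike real neighbouring bands, so the rate for band permutations does not cover such dependence. Band permutations within groups of background were not simulated. With a large planted effect (thinned dark bands, a difference of 1 SD, a correlation of 0.8), all 200 runs of each had p under 0.05. Smaller effects were not simulated, so the power to detect them is unknown. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

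The description of the list, its stricter version (the highest 50% of folds, 57924 peaks with ties), the merging of overlapping rows and the naming of the 10 strongest peaks by fold were fixed before the data were examined. The tests on bands, chromosomes and spacing, and the use of the strongest 10%, were chosen after seeing the data. The stalk, variable and centromeric classes were left out of the rotation test. Replicate concordance was not run, since there were no values per replicate. Promoter and gene classes, motifs, gene lists and peaks at single genes were fixed for analysis but not run, because no sequence or annotation of hg19 was used here. The RefSeq table, of assembly GRCh38.p14, gave the order of genes on chromosome 11, from which ELF5 and EHF were found to be neighbours, and none of its coordinates are printed. Its protein-coding gene counts per chromosome were used in a first version of the chromosome comparison, which was replaced by peaks per Mb after its result had been seen, because the build differs. Broad peaks were those of at least 2000 bp.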

Results

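Binding of ELF5, an ETS-family transcription factor of luminal and alveolar epithelium, was mapped by ChIP-seq in T47D, an established human luminal A breast epithelial line grown with insulin. The series held 3 ELF5 ChIP replicates and 1 input sample, and the data analysed here were 1 list of ELF5 peaks on hg19. Whether the list rests on all 3 replicates or on replicates 1 and 3 is not given in the sources used here. The list gave no value per replicate, so no spread between replicates could be attached to any peak and no group could be tested against another. The title of the series concerns ELF5, EHF and epithelial integrity, and the question addressed here is where ELF5 bound. All positions are on hg19 and counted from 1.

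The ELF5 peaks in this list were numerous, narrow and mostly weak, traits that depend on where the list was cut. The authors' p per peak ran up to 0.00982 and their q up to 0.583, so weakly supported peaks were kept. The smallest width, 135 bp, was shared by 10693 peaks. The list held 115384 peaks with a median fold enrichment over the local background of 3.66, and the interquartile range ran from 2.98 to 5.50. The strongest 10% of peaks by fold, called strong peaks here, numbered 11542 with ties, began at a fold of 11.99 and had a median of 18.8. Strong peaks were also wider, with a median of 818 bp against 201 bp for the others. Of 517 peaks of at least 2000 bp, 428 were strong. The broadest peak covered 5845 bp in band 19p13.3, from 1248171 to 1254015 on chromosome 19, with a fold of 45.6.

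The depth behind a typical peak was low. The fragment pileup recovered at the peak had a median of 16, for which the exact Poisson 95% interval runs from 9.15 to 26.0. At a pileup of 16 and a fold of 3.66, the interval of the fold ran from 2.19 to 5.79, so typical peaks could not be ranked against each other at this depth. Strong peaks had a median pileup of 92. These intervals cover counting error only, hold the background fixed, and do not allow for the choice of the summit as a maximum. The authors' q was 0.05 or more for 14394 peaks, which is 12.5% of the list.

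**Figure D1:**
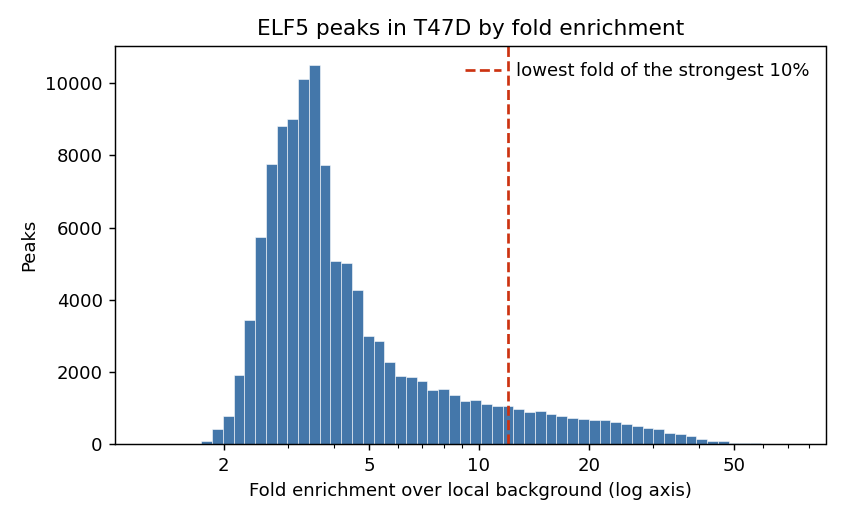
Number of ELF5 peaks by the authors' fold enrichment over local background, on a log axis; bars are 60 equal steps of log fold. Most peaks lie near the median of 3.66, and the dashed line marks the lowest fold of the strongest 10%, 11.99.

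The 10 strongest peaks by fold lay in 10 different bands, at folds from 64.3 to 72.5. The strongest, in 6q23.2, covered chromosome 6 from 134274006 to 134274659 with a fold of 72.5 (95% counting interval 63.7 to 82.2). It was followed by a peak in 2q36.1 on chromosome 2 from 224821875 to 224822538, with a fold of 70.5 (61.5 to 80.5), and one in 18p11.31 on chromosome 18 from 3261628 to 3262714, with a fold of 70.2 (61.2 to 80.2). The others were in 2q24.1, 19p12, 13q32.2, 19q13.32, 4q31.1, 9p13.3 and 18q12.2. The intervals of these 10 overlapped, so their order was not resolved. Only the peaks in 6q23.2 and 9p13.3 were also among the 10 with the smallest p. The 10 by fold lay over backgrounds from 1.81, the lowest in the list, to 3, and the 10 by p over backgrounds up to 7. A low background raises the fold, so the ranking by fold favours such sites. The 9p13.3 peak, on chromosome 9 from 33220817 to 33221786, ranked first by p with a pileup of 285 over a background of 3. Genes at these positions were not analysed here.

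Peaks were concentrated in the lightly staining Giemsa bands, which are textbook gene-rich chromatin. Unstained bands (gneg) held 59.1 peaks per Mb and the palest stained class (gpos25) 63.5, against 30.9 in gpos50, 17.0 in gpos75 and 10.3 in gpos100, the darkest class. Strong peaks followed the same order, from 7.01 per Mb in gpos25 to 1.06 in gpos100. Centromeric bands held 6.88 peaks per Mb, variable heterochromatin 2.89, and the stalk bands none. These densities use full band lengths, with assembly gaps not taken out, so low values in these 3 classes are no evidence of absent binding. Light bands (gneg and gpos25) hold 53.5% of the euchromatic bases and held 78.6% of the euchromatic summits, against a mean of 55.9% over 10000 rotations of the summits along each chromosome. The two-sided permutation p was 0.0001, the smallest these rotations can give. The share was 77.7% for strong peaks, with the same permutation p.

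**Figure D2:**
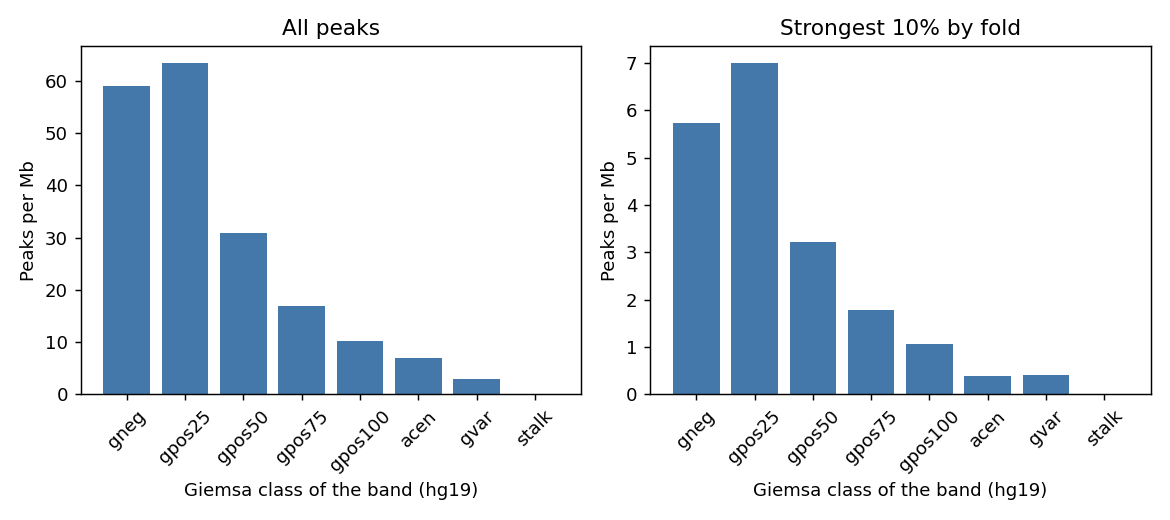
ELF5 peaks per Mb in each Giemsa class of hg19 bands on chromosomes 1 to 22 and X, for all peaks (left) and the strongest 10% by fold (right). Density falls from gpos25, 63.5 and 7.01 per Mb, to gpos100, 10.3 and 1.06 per Mb.

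Among 623 euchromatic bands of at least 2 Mb, the densest were 9q34.3 with 391 peaks per Mb, 7p22.3 with 388.6, 17q25.3 with 309 and 20q13.33 with 287, all at chromosome ends. By strong peaks the order was different. Band 11q13.1 came first with 35.6 strong peaks per Mb, followed by 19q13.32 with 25.7, 19p13.3 with 24.5 and 9q34.11 with 23.4. The lists of the 10 densest bands by all peaks and by strong peaks shared 3 bands. Of the 10 densest by all peaks 6 were terminal, and of the 10 densest by strong peaks 2.

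Terminal light bands held more peaks, with a smaller share of strong ones, than interior light bands. The 40 terminal bands with at least 20 peaks held 136 peaks per Mb against 53.7 in 389 interior bands, a ratio of 2.52. The mean share of strong peaks was 8.23% ± 5.32 (SD over bands) in terminal bands and 12.96% ± 6.61 in interior ones. The two-sided permutation p over bands was 0.0001 for both differences, the smallest these permutations can give. The difference in share, -4.72 percentage points, was -2.76 with the strongest 5% of peaks and -7.55 with the strongest 20%. Strong peaks alone were 1.54 times denser in terminal bands (permutation p = 0.0016). Neighbouring bands are not independent, so these p-values describe the arrangement of bands in this list. The bands were pooled over chromosomes, which themselves differ in peak density, and how far that contributes was not tested.

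**Figure D3:**
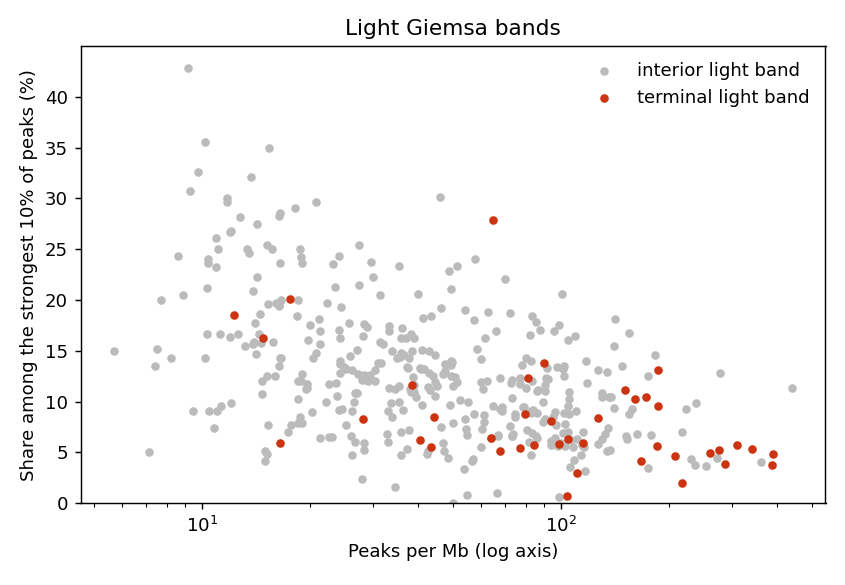
Each point is a light Giemsa band with at least 20 peaks; the horizontal log axis gives peaks per Mb and the vertical axis the percentage of the band's peaks among the strongest 10%. Terminal bands (red) average 8.23% strong peaks and interior bands (grey) 12.96%.

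Chromosomes differed 10.1-fold in peak density, from 9.85 per Mb on X to 99.6 on chromosome 17, and chromosomes 19 and 20 followed with 93.6 and 82.5. Strong peaks were densest on chromosome 19, at 15.4 per Mb. The share of peaks that were strong was highest on X, at 17.6%, followed by chromosome 19, at 16.4%. Their median backgrounds were low, 2 and 2.08, and a low background can raise this share because fold is a ratio to it. Chromosomes 18, 22, 2 and 13, with median backgrounds from 2 to 2.13, had lower shares of 12.52%, 11.01%, 13.12% and 12.02%. These shares were above the median over chromosomes, 9.86%. A low background alone therefore did not set X and chromosome 19 apart. Over 23 chromosomes, peak number was not detectably related to chromosome length (Pearson r = 0.385, permutation p = 0.0704, adjusted p = 0.0939; Spearman rho = 0.362, permutation p = 0.0914, adjusted p = 0.104). Without chromosomes 1 and 2, r was 0.206 (permutation p = 0.367) and rho 0.296 (permutation p = 0.192). For the number of strong peaks against length, r was 0.457 (permutation p = 0.0279, adjusted p = 0.0675) and rho 0.404 (permutation p = 0.0572, adjusted p = 0.0915), and without chromosomes 1 and 2 r was 0.181 (permutation p = 0.431) and rho 0.262 (permutation p = 0.252).

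Peak density per Mb was related by rank to the median local background of a chromosome's peaks, which ran from 2 on X and 18 to 4 on 11 (rho = 0.600, permutation p = 0.0030, adjusted p = 0.0240). Pearson's r was 0.441 (permutation p = 0.0338, adjusted p = 0.0675), and without X and 18 it was 0.318 (permutation p = 0.159), with a rho of 0.486 (permutation p = 0.0266). For strong peaks per Mb, rho was 0.451 (permutation p = 0.0322, adjusted p = 0.0675) and r 0.0442 (permutation p = 0.861, adjusted p = 0.861), and without X and 18 rho was 0.290 (permutation p = 0.201) and r -0.0880 (permutation p = 0.723). Adjustment was by Benjamini-Hochberg over 8 tests of 4 relations.

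Peaks lay closer together than their bands' densities give. The median distance between neighbouring summits was 4186 bp, against a mean of 8900 bp when the same number of summits was placed at random within each band. The smallest distance was 71 bp, so some neighbouring peaks may be parts of 1 enriched stretch. Such peaks were not joined before the test, and part of the closeness may come from them. The one-sided permutation test counted distances of at most 12.5 kb, which made up 69.9% of the distances and 59.1% on average after placement (p = 0.0010, the smallest 1000 placements can give). Joining peaks within 12.5 kb gave 34316 regions, of which 18078 held 1 peak and 2034 held 10 or more. The regions of 10 or more held 43.0% of all peaks but 32.0% of strong peaks. The region richest in peaks, in 7p22.3 from 841466 to 1798455 on chromosome 7, held 460 peaks, of which 21 were strong. The region richest in strong peaks, in 9q34.3 from 139835540 to 140218386 on chromosome 9, held 258 peaks, of which 29 were strong.

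Band 11p13 carries ELF5 and EHF, 2 ETS genes that have no protein-coding gene between them in the RefSeq table for GRCh38. It held 211 peaks, of which 23 were strong. Its density of 39.1 peaks per Mb was above that of 156 of 301 unstained bands of at least 2 Mb, whose median was 37.7, and its 4.26 strong peaks per Mb lay near their median of 4.41. The strongest peak of the band covered chromosome 11 from 32605088 to 32605940, with a fold of 26.6 (22.8 to 30.8). The next 2 were at 33060571 to 33061741, with a fold of 26.0 (21.7 to 30.97), and at 35683891 to 35685017, with a fold of 25.5 (21.8 to 29.6). Which of these peaks lie at ELF5 or EHF was not analysed here.

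**Figure D4:**
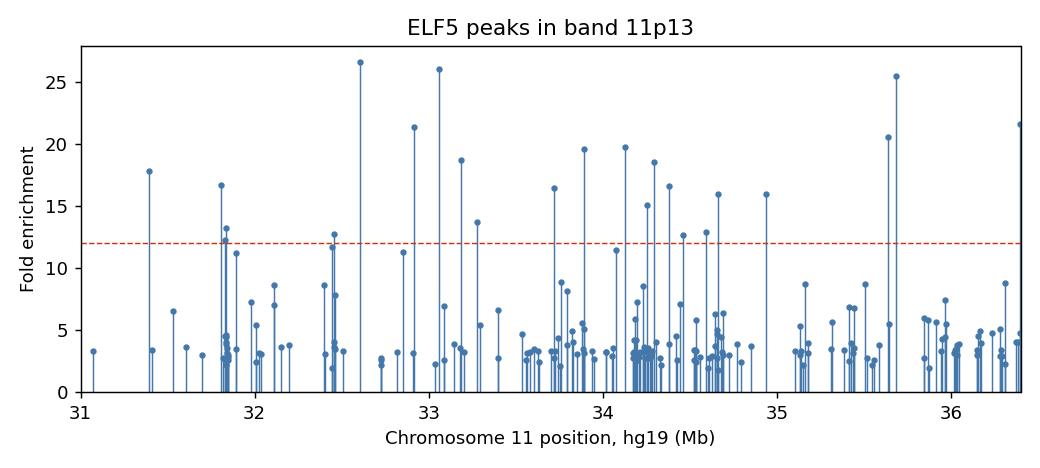
Each line is an ELF5 peak in band 11p13 at its summit on chromosome 11 (hg19, Mb), its height the authors' fold enrichment; the dashed line marks the lowest fold of the strongest 10%, 11.99. The highest of the 211 peaks reaches a fold of 26.6.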

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

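Every test in this part was chosen after its result or related values were seen, except the comparison within 3 equal groups of bands by background, which was set out before its result was seen. Chromosome Y, outside the chromosomes compared, held 24 peaks, 23 of them with the authors' q under 0.05, at a median fold of 2.99, and none was strong. Their median background was 7, against 3.105 over the whole list, and whether they are ELF5 sites on Y was not tested.

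Terminal light bands held 2.52 times the peak density of interior ones with a smaller share of strong peaks. A higher background as the cause of the smaller mean share is argued against by the bands' median background, 2.76 in terminal and 2.86 in interior bands. With medians this close, grouping by background could hardly have shrunk the difference, so the grouped value adds little. Within 3 equal groups of bands by background it was -5.25 percentage points (permutation p = 0.0001, the smallest possible), against -4.72 without the grouping. From the lowest to the highest group the share fell in both kinds of band, from 16.2% to 9.76% in interior and from 10.9% to 4.12% in terminal bands. Peaks with −log10 q under 5 make up part of the higher density, but not all of it. The ratio was 1.82 among peaks with −log10 q of 5 or more and 1.54 among strong peaks (permutation p = 0.0016). The cut at 5 lies above the list's median −log10 q of 3.18, so peaks close to the caller's threshold were not told apart from other weak ones. Pooled over bands, the share of strong peaks was 6.70% in terminal and 10.98% in interior bands. This restates the lower density ratio for strong peaks and is not a separate result. Whether peaks close to the threshold account for it was not tested. Base composition and gene density stay open, as no sequence or annotation of the build was used, and no biological explanation was tested.

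Chromosomes with a higher background had more peaks per Mb, and greater depth there, from copy number for example, may lift weak sites over the threshold. With −log10 p of 5 or more, rho was 0.532 (bootstrap 95% interval 0.0767 to 0.863), and after thinning every chromosome to a background of 2 it was 0.314 (-0.193 to 0.737; permutation p = 0.145). Pearson's r went from 0.290 (permutation p = 0.179) to -0.102 (permutation p = 0.677). A first version per protein-coding gene, with gene counts of another build, was set aside for that build after its relation was seen to be gone on thinning, so the choice of peaks per Mb matters here, and depth and other differences between chromosomes cannot be told apart: the interval of rho per Mb spans both outcomes.

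Peaks over a background of at least 20 fragments numbered 66, with a median fold of 2.26, and the highest background was 256.0, in 6p11.1. Repeats near heterochromatin that the build holds in too few copies are a candidate explanation. Of these peaks 45.5% lay in or within 2 Mb of centromeric, variable or stalk bands, against 3.50% of the others, a ratio of 12.99 (Fisher's exact p = 3.68e-26, two-sided). Such peaks cluster, so this p is too small, and the other peaks over a high background stay unexplained.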

How the results depend on the processing

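The stricter list and the merging of rows were set before the data were examined, and all other alternatives were chosen after seeing the data. Of 32 alternative values, 6 moved, none changed direction and 26 did neither. A tested value counted as moved if its unadjusted permutation p crossed 0.05, a count if it differed by over 1.5 times, and a median if it left the 95% interval of the main median, which is narrow with this many peaks. The rho of peak density with background therefore counted as unmoved for strong peaks (permutation p = 0.0322). Its adjusted permutation p was 0.0675 for strong peaks, against 0.0240 for all peaks. In the stricter list, the highest 50% of folds by construction, there were 57924 peaks, the median width was 307 bp, the median fold 5.49 and 11p13 held 103 peaks. Among peaks with q under 0.05, the median width was 227 bp and the median fold 3.91. Merging overlapping rows changed nothing, since no rows overlap. The share of summits in light bands ran from 77.1% to 78.6% over its alternatives. The ratio of terminal to interior density fell from 2.52 to 1.54 for strong peaks. The terminal minus interior share of strong peaks, -4.72 percentage points for the strongest 10%, was -2.76 for the strongest 5%, -7.55 for the strongest 20% and -4.95 for the strongest 10% by p. Leaving out replicates, a global IDR threshold and every alternative that needs sequence or annotation were not run. No paired analysis was possible because the list holds no value per replicate. Low pileups limit the ranking of typical peaks.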

Other observations

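The median background of peaks differed between chromosome arms, from 1.81 on Xq and 2 on 4q, 6q, 18p and 18q to 4.05 on 3q and 4.17 on 11q. The highest medians among bands of at least 2 Mb were 7 in 3q29 and 6.0 in 3q26.32 and 3q26.33, followed by 5.80 in 11q24.3. In 11q25 only 3 of 439 peaks were strong, 0.68%, at a median background of 5.00. The other bands named here had higher backgrounds and larger shares of strong peaks. These were 5.91% in 3q29, 13.75% in 3q26.32, 12.05% in 3q26.33 and 3.31% in 11q24.3. A high background alone therefore did not set 11q25 apart.

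Strong peaks stood alone more often than the others. After joining peaks within 12.5 kb, 23.02% of strong peaks were the only peak of their region, against 14.9% of other peaks, a difference that was not tested.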
